A study of Bos taurus with 6 samples.

How the data were processed

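RNA from 6 samples of bovine mammary epithelial cells was measured by mRNA sequencing. The growth protocol calls the cells MAC-T, an immortalised line of bovine mammary epithelium. Per the labels, 3 samples had been transfected with a miR-199a-3p mimic and 3 with a negative control (NC) mimic, each at 50 nM, and were collected after 48 h. A mimic is a synthetic small RNA that supplies the activity of a microRNA. Total RNA was extracted with TriZol and libraries were made with an mRNA kit from ABclonal, per the labels' protocols. The labels say that the experiment was in triplicate and do not say how far the cultures were separate. All p-values therefore measure the spread between these samples, which may be technical.

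The deposited files hold raw counts per gene ID, 1 file per sample, with 28522 rows each. The submitters' processing notes name HISAT2, DESeq2 and the genome build UMD3.1, without versions or roles. The counting tool, the annotation release and the strand setting are not given in the sources used here. Reads shared between overlapping, antisense or near-identical genes could therefore not be told apart. Of the rows, 27270 carried Ensembl gene IDs and 1252 carried IDs of another kind, called rows without an Ensembl ID below. How the latter were defined is not given in the sources used here.

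The files do not pair the IDs with gene symbols. The gene table used as reference, of 37063 bovine genes, gave a symbol to 0 of the IDs because its column for Ensembl IDs was empty. No gene names, gene functions or coordinates are therefore given. Pathway lists, cell type markers, mitochondrial and ribosomal protein shares, and the genes to be named in every case (IL6, CXCL8, IL1B, TNF, CCL2, TLR4, NFKB1, MTOR, MET, CD44, CAV2 and PTGS2) were fixed before the data were examined and were not analysed here. Sites for the miR-199a-3p seed in 3′ UTRs were not analysed here either, as no genome or transcripts were used.

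Counts were tested with the quasi-likelihood F test of edgeR 4.0.16 (two-sided) in R 4.3.3, with TMM normalisation and group as the only term. Rows were kept by the default filter of edgeR, which uses a minimum count of 10 and a minimum total of 15. P-values were adjusted by the Benjamini-Hochberg method over all rows tested, and a row was called changed at an adjusted p under 0.05. Fold changes are mimic over NC. The alternatives used limma 3.58.1 (voom) and DESeq2 1.42.0, other scalings, filters and thresholds, the replicate number as a block, and the omission of each library. This design and the alternatives were fixed before the data were examined. Plots were drawn with matplotlib 3.10.9.

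The rule for named genes took rows past the threshold by absolute log2 fold change. They needed a mean of at least 20 counts in the higher group, no overlap between the groups in CPM (counts scaled to the library's total over the rows tested times its TMM factor), and a symbol. As no row had a symbol, that condition was dropped and only 2 rows per direction were taken. Apart from a symbol, 1025 rises and 611 falls met the rule. Of the 4 rows, 3 had no Ensembl ID and are described by their rank.

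Measures of each library were compared by exact permutation tests, two-sided, for which 3 against 3 libraries cannot give a p below 0.1. The procedure was tested on simulated counts for 13949 genes with 100 genes changed 1.5-fold and 100 changed 2-fold. In this simulation of the comparison of mimic with NC, edgeR recovered 51% of the 1.5-fold and 77% of the 2-fold changes. All recovered changes had the right sign, and 6.57% of the calls were false. The 77% lay below the minimum of 80% first set for this test, which was lowered to 60% after the value was seen. DESeq2 recovered 61% and 78%, with 14.7% of its calls false. Limma-voom recovered 52% and 73%, with 6.72% false. These rates came from a single simulated set with the same dispersion in both groups and no outlying library. The real groups were unequally spread, so the rates need not hold for them.

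Total counts per library ranged from 16303257 to 23720655. A floor of 3 counts corresponded to 0.126 to 0.184 CPM when scaled to the library total alone, which covers counting error only. No library was within sampling noise of another of its group, as the chi-square per degree of freedom of same-group pairs was 2.68 to 37.9. The spread was unequal, at 2.68 to 4.20 for mimic pairs and 8.40 to 37.9 for NC pairs. The edgeR fit used the same dispersion of a gene in both groups, so its p-values rest on a spread averaged over unlike groups.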

Results

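Gene expression was profiled in bovine mammary epithelial cells 48 h after transfection with 50 nM of a miR-199a-3p mimic or of a negative control (NC) mimic, with 3 libraries per group. The NC libraries held 23720655, 22197871 and 16303257 counts for replicates 1, 2 and 3. The mimic libraries held 18198903, 19392853 and 19006481. The NC totals varied more than those of the mimic libraries and lay on both sides of them. Between 16995 and 17541 of the gene rows had at least 1 count in a library. Across the 6 libraries, 19569 rows had a count and 8953 were at 0 throughout.

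The comparison of the mimic with NC asked which transcripts changed when miR-199a-3p was supplied, in a series on the part of this microRNA in inflammation of these cells. Of 13949 genes tested, 1643 (11.8%) changed, of which 1029 rose and 614 fell with the mimic. Most changes were small. The median rise was 0.47 on the log2 scale (1.38-fold, interquartile range 0.34 to 0.72), and the median fall was -0.40 (1.32-fold, -0.57 to -0.30). The median standard error of the called genes was 0.085. A change of at least 2-fold was estimated for 157 of the called genes, 120 that rose and 37 that fell. These counts were 183 and 52 without NC replicate 2, and 70 and 12, 72 and 16, and 79 and 15 without mimic replicates 1, 2 and 3. In all 1029 rises and all 614 falls the 3 libraries of one group lay above the 3 of the other. Over all genes tested this held for 4770 (34.2%), where chance gives 10%.

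These calls came from the edgeR quasi-likelihood test at an adjusted p under 0.05, and the biological coefficient of variation was 10.9%. This value was fitted for both groups together, though the NC libraries varied more than the mimic libraries. With library size as the only scaling, 768 genes rose and 1010 fell, so that 43.2% of the calls were rises against 62.6% with TMM. The number of calls was 3460 without NC replicate 2, 951 without NC replicate 3, and 472, 510 and 520 without mimic replicates 1, 2 and 3.

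**Figure D1:**
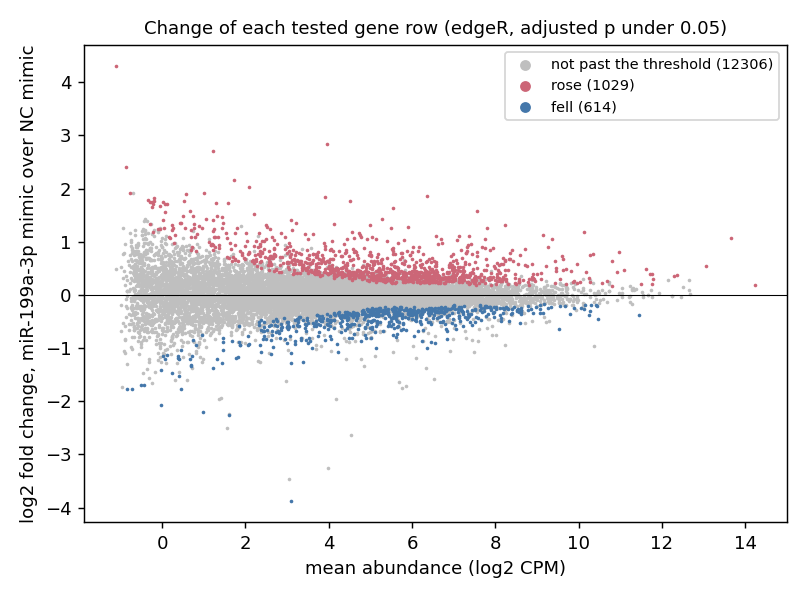
Log2 fold change of mimic over NC (vertical axis) against mean abundance in log2 CPM (horizontal axis) for the 13949 genes tested, each point 1 gene. The 1029 genes that rose are red, the 614 that fell are blue and the others are grey.

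The largest rise among genes with at least 20 counts in the higher group was in a row without an Ensembl ID. It went from 3.83 ± 0.136 CPM in NC to 27.3 ± 0.634 CPM in mimic libraries (SD, n = 3). Its log2 fold change was 2.83 with a standard error of 0.10 (7.10-fold, edgeR adjusted p = 4.98e-06). The second largest rise, also in a row without an Ensembl ID, went from 0.605 ± 0.0665 to 3.95 ± 0.406 CPM. Its log2 fold change was 2.71 with a standard error of 0.22 (6.53-fold, edgeR adjusted p = 0.000205), and its NC libraries held 15, 12 and 11 counts.

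By the same rule, the largest fall was in ENSBTAG00000054661, which went from 15.8 ± 9.42 CPM in NC to 1.07 ± 0.173 CPM in mimic libraries (SD, n = 3). Its log2 fold change was -3.87 with a standard error of 0.49 (edgeR adjusted p = 0.00217). Its NC libraries were spread widely, at 7.16, 14.4 and 25.8 CPM for replicates 1, 2 and 3, all above the mimic libraries. The second largest fall, in a row without an Ensembl ID, went from 4.77 ± 1.93 to 0.984 ± 0.338 CPM. Its log2 fold change was -2.26 with a standard error of 0.36 (edgeR adjusted p = 0.00602).

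**Figure D2:**
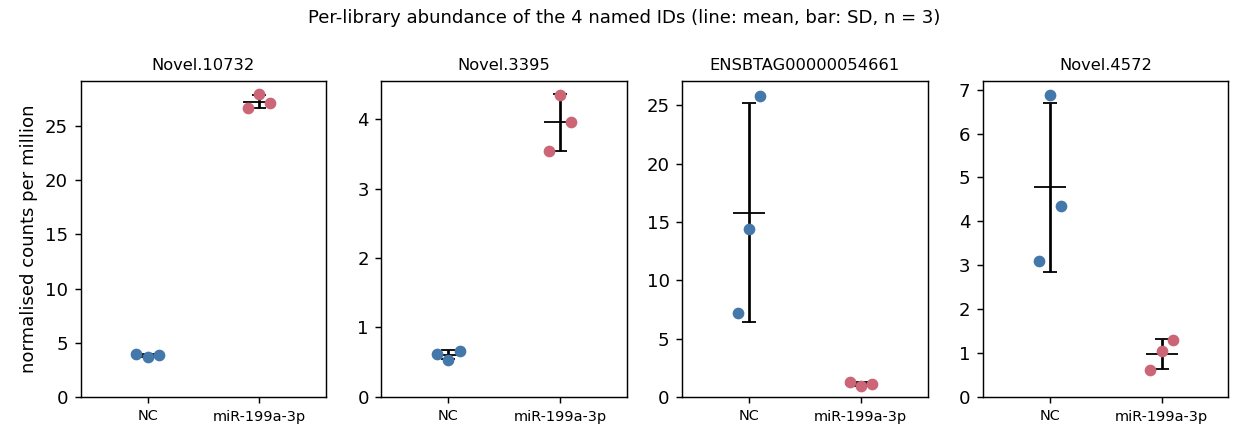
CPM scaled by TMM (vertical axes) of the 4 rows described, in NC (blue) and mimic (red) libraries, with each point 1 library, the line the mean and the bar the SD (n = 3). ENSBTAG00000054661 varied between 7.16 and 25.8 CPM in NC libraries.

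The genes that rose included some of the most abundant transcripts. Of the 10 most abundant rows, 5 rose, 0 fell and 5 did not pass the edgeR threshold. They were ranked on the mean of all 6 libraries, which leans towards rows that rose. The rises of ranks 1 and 10 lay near the threshold (edgeR adjusted p = 0.0486 and 0.0442). Of the 2790 most abundant genes tested, 362 rose and 202 fell. The second most abundant row took 0.849 ± 0.0882% of the counts in NC and 1.72 ± 0.0359% in mimic libraries (SD, n = 3). Its log2 fold change was 1.07 with a standard error of 0.07 (edgeR adjusted p = 8.83e-05). This row was singled out after its values were seen. The 10 most abundant rows of each library, ranked within that library, together took 7.41 ± 0.261% of its counts in NC and 8.98 ± 0.110% in mimic libraries. The difference of 1.58 percentage points gave an exact permutation p of 0.1 (two-sided), the smallest that 3 against 3 libraries can give, and 0.2 after adjustment over 4 measures. The share of counts on rows without an Ensembl ID was 1.54% in both groups (exact permutation p = 1).

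All genes that rose together took 15.4 ± 0.314% of the counts in NC and 20.4 ± 0.153% in mimic libraries. All genes that fell took 7.23 ± 0.0574% and 5.52 ± 0.0623% (SD, n = 3). These genes were chosen on the same libraries, so the shares were not tested. No row was at 0 in every library of one group with a mean of at least 20 counts in the other.

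Changes were called more often among abundant genes. In 5 classes of equal size from the lowest to the highest mean abundance, 4.59%, 9.53%, 10.8%, 13.7% and 20.2% of the genes tested changed. The median absolute log2 fold change of the called genes went the other way, at 1.21, 0.65, 0.45, 0.37 and 0.34. At low counts only large estimated changes could pass the threshold, so neither trend shows that rare and abundant genes responded differently. Rises were 70.3%, 63.9%, 59.9%, 59.0% and 64.2% of the calls in these classes.

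Of 12995 genes with Ensembl IDs, 1557 (11.98%) changed, 979 that rose and 578 that fell. Of 954 rows without one, 86 (9.01%) changed, 50 that rose and 36 that fell. The odds ratio for rows without an Ensembl ID was 0.728 (Fisher's exact test, two-sided, p = 0.00575, across genes, which are not independent replicates). Within deciles of abundance the direction turned, with a common odds ratio of 1.27 (95% interval 1.00 to 1.62). The median abundance was 3.43 CPM for these rows and 24.5 CPM for genes with an Ensembl ID.

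The libraries of the groups separated on the first principal component of log2 CPM, which held 43.4% of the variance. The second component, with 26.1%, set NC replicate 2 apart from the other NC libraries. NC replicate 2 also stood apart on the first, at -30.3 against -12.0 and -13.6 for NC replicates 1 and 3. This was on the side away from the mimic libraries (17.9 to 19.7). Pairs of mimic libraries correlated at 0.993 to 0.994 across genes, which are not independent replicates, and pairs from different groups at 0.980 to 0.988. NC replicate 2 correlated with the other NC libraries at 0.985, against 0.993 for NC replicates 1 and 3. With the mimic libraries NC replicate 2 correlated at 0.980 to 0.981, and NC replicates 1 and 3 at 0.986 to 0.988. NC replicate 2 was thus less like its own group than NC replicates 1 and 3 were like the mimic libraries, and was the NC library least like these. Without NC replicate 2, all 1643 called genes had the same direction, 1633 of them were called again, and 3460 genes were called in all. The groups did not overlap for any of these 1643 genes, so their direction could hardly have turned.

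**Figure D3:**
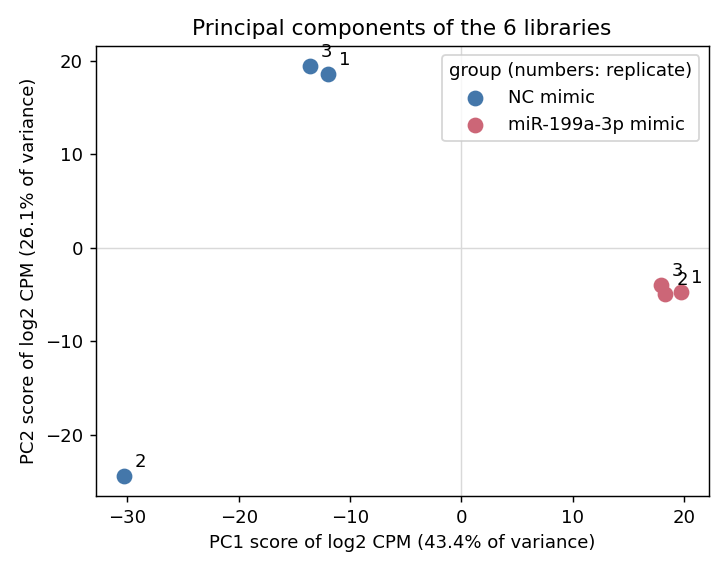
First (horizontal axis, 43.4% of variance) and second (vertical axis, 26.1%) principal component scores of log2 CPM for the 6 libraries, each point 1 library with its replicate number, NC in blue and mimic in red. The mimic libraries lie together, and NC replicate 2 lies apart from NC replicates 1 and 3.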

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

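The number of changed genes stayed between 1608 and 1778, against 1643, with other scalings (RLE, upper quartile, library size only), without the 10 most abundant rows, without a filter or with a stricter one, and with limma-voom or DESeq2. With library size as the only scaling 1010 genes fell. At an adjusted p under 0.01, 497 genes passed (361 rose, 136 fell), and with an absolute log2 fold change of at least 1, 157 passed (120 rose, 37 fell, or 70 to 183 and 12 to 52 without 1 library). Leaving out 1 library gave 472 to 3460 changed genes, 351 to 1861 that rose and 121 to 1599 that fell, the highest without NC replicate 2 and the lowest without mimic replicate 1. Each used fewer samples, and the cause of the higher numbers without NC replicate 2 was not tested. No gene called in the reported fit changed sign in any of these. The other thresholds reused the same fit, so their signs were given. For the omission of 1 library a change of sign was nearly precluded, as the groups did not overlap for any called gene. The 4 rows described kept their direction and their call in all 17 alternatives, though they had been picked as large changes without overlap between the groups. The difference in the share of each library's own 10 most abundant rows was 1.43 to 1.68 points.

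With the replicate number as a replicate block, 1411 genes changed (909 rose, 502 fell). Deviations of same-numbered samples correlated at 0.003 to 0.054, and NC replicate 3 did not correlate best with its own number, so the numbers were not taken to pair the samples.

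The other settings fixed for gene lists, seed sites and shares of mitochondrial and ribosomal protein genes were not run, since no ID had a symbol or sequence. Among the genes of lowest abundance the median absolute log2 fold change of the calls was 1.21, against 0.34 among the most abundant. Rare genes needed larger estimated changes to pass the threshold, and calls were not recomputed at lower depths.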

Other observations

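The test of a swapped label and its bound, the test of a partial mimic effect, the comparison of NC replicate 2 with the rest of its group, the simulations and overlaps beside it, the positions of NC replicates 1 and 3, the intervals of the lower rows, and the decision to read no support from a count set against 0 were chosen after the position of NC replicate 2 or the value concerned had been seen.

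The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 1643 genes with edgeR and was the only 1 of the 10 to give as many. The highest of the others gave 0 with edgeR and 0 with limma-voom, against 1608 for the real split. At an unadjusted p under 0.05 edgeR gave 153 to 561 genes in the others and 3847 in the real split. Each of the other splits mixed NC and mimic libraries on each side. A difference between the groups, whatever its cause, therefore added to the spread within each side and made few calls likely beforehand. The splits also cannot tell an effect of the mimic from another difference between the groups, so no conclusion is drawn from them.

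NC replicate 2 stood 1.46 times as far from the other NC libraries as these stood from each other, and 2344 genes differed between it and them (1311 higher, 1033 lower; 235 and 27 by at least 2-fold), with its own spread assumed to be that of the other libraries. Depth is argued against, as the ratio was 1.44 (1.43 to 1.45 in 20 draws) after thinning to the smallest total. A swapped label is argued against too. NC replicate 2 lay 0.290 of the way from NC (0) to mimic (1) on 3442 of the genes called without it. The mimic libraries, at 0.976 to 1.01, set the upper end of this scale and are no independent reference. NC replicates 1 and 3, each left out in turn, lay at 0.162 and 0.104, on other gene sets (1256 and 949 genes). A partial mimic effect as the whole cause is argued against. Of the differences of NC replicate 2, 8.40% were moved the same way and at least as far by the mimic. In 20 simulations of such an effect, set at 0.290 of the mimic's, this held for 50.9% to 53.9% of as many top genes. It held for 4.01% to 5.72% in 20 simulations with no change. The simulations of the effect called 41 to 79 genes, against 2344 here, so most of their top genes were uncalled. The lists are therefore unlike, but such an effect gave far fewer called genes than were seen. As part of the cause, a partial mimic effect stays open. The same sign as the mimic's change was seen in 63.1% of the differences. This share was 79.4% to 83.8% with no change, where at most 6 genes were called and the shared NC libraries set the sign. It was 89.4% to 91.4% in the simulations of the effect. For the mimic over NC replicates 1 and 3, 361 higher and 296 lower genes were called the same way. Independent lists, which leave out these shared libraries, would give 179 and 114. Neither measure decides. Reads from other cells stay open, as the excess of higher over lower genes at 2-fold goes with them, while the 5 rows with at least 20 counts there and at most 3 in each other library held only 417 counts (0.00188% of the library), and of the 23 rows with at least 20 counts estimated to be at least 2-fold lower, where 0 were predicted for an admixture of under 50%, only 1 had a 95% interval wholly beyond 2-fold, and no biological explanation was tested.

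More genes rose than fell, and scaling may decide this for the calls as a whole. The lowest share of rises over the other scalings (RLE, upper quartile, library size only) was 43.2%, with library size only. That scaling moved the median of all tested genes to -0.06 on the log2 scale. Among calls of at least 2-fold the excess of rises held under each scaling, at 69.3% or more. This argues only against scaling differences as small as those run, which could hardly move enough genes across a 2-fold threshold. A larger shift was not tested. A single library as the whole source of the excess is argued against for the calls as a whole. Their share of rises was 53.8% or more without each library in turn. It was lowest without NC replicate 2 (1861 rose, 1599 fell), against 62.6% with all libraries. How much of the excess came with NC replicate 2 was not tested. An effect of the mimic stays open as a hypothesis for the 2-fold calls.

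Rows without an Ensembl ID were called less often than genes with one. Lower abundance is a candidate explanation, as within abundance deciles the common odds ratio was 1.27 (95% interval 1.00 to 1.62, its lower bound just above 1), so that the deficit was absent. The interval met neither of the outcomes set beforehand, which were one that includes 1 and one wholly below it, and the explanation is left undecided.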
